A study of Mus musculus with 3 samples.

How the data were processed

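The study, a set of single-cell RNA libraries from mouse lung, holds 3 libraries, 1 per group: wild type with PBS, wild type with bleomycin, and Bcat2 heterozygous with bleomycin. Per the labels, the mice were male C57BL/6, 10 to 12 weeks old, and bleomycin was put into the trachea at 1.25 mg/kg 14 days before lungs were taken. Whether a library holds 1 lung or several was not given in the sources used here. Per the labels' protocols, lungs were cut up, digested with a tumor dissociation kit, freed of red cells by lysis and run on a DNBelab C4 droplet system for 3' libraries. The deposited matrices hold raw UMI counts per gene symbol and barcode, written by PISA 1.0 per the file headers. The submitters' processing notes name Seurat and GRCm39, while aligner, annotation and the treatment of intronic reads were not given in the sources used here. No genome coordinates were used. Every barcode held at least 1000 UMIs, which the values show and no source states.

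The libraries held 9657, 7467 and 14064 barcodes and 84124376, 74909958 and 142644861 UMIs over 39375, 39817 and 40665 gene symbols. Kept cells had at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs, which removed 15, 6 and 3 barcodes. Scrublet, run per library in scanpy 1.11.5 with an expected rate of 0.06, called 284, 37 and 508 doublets (2.95%, 0.496% and 3.61%), and these were removed. Its automatic thresholds were 0.233, 0.390 and 0.215, and at under 0.5% of cells the call for WT bleomycin was taken as not having worked, and the doublets left in that library were not measured. A common threshold of 0.233, an alternative chosen after seeing the data, calls 284, 84 and 457. The kept cells carried 80438987, 74410832 and 134642154 UMIs. At that depth a gene with 3 UMIs over all cells stands at 0.0373, 0.0403 and 0.0223 CPM.

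All 30335 cells were clustered together without integration. Counts were scaled to 10000 per cell and logged, 3000 variable genes were ranked within libraries (20 expression bins, genes in at least 20 cells), and scaled values were limited to 10. Every gene of the gene lists was left out of the variable genes. A graph of 15 neighbours on 30 principal components, with at least 2 shared neighbours, was clustered by Leiden at resolution 1.0 with 4 iterations and seed 1, giving 35 clusters. Fibroblast-like cells were clustered again at 0.5. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with edgeR 4.0.16 in R 4.3.3 for TMM factors.

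Markers were fixed for 26 classes and 4 fibroblast states. A cluster took the class with the highest median, over markers, of log2(CPM + 50) minus the gene's median over clusters, with 3 of the states rolled up into fibroblast. It stayed unnamed with fewer than 3 markers at 0.1 UMI per cell, or with another class holding more, or at least 2, of the 10 leading genes. So did a cluster whose median UMI number was under 0.333 of its library's with no marker among the 10, and a sub-cluster with no marker among them. This rule was the last of 6 tried after the clusters and their cells per library had been seen, and it was settled before any gene or list value was computed. The last 2 rules gave the main clusters the same names, and rules 3 and 4 differ from them in the cluster led by Hmga2. Rules 1 and 2 gave another name, or none, to the clusters led by Grem1 and by Hmga2, to the one led by Aspn (755 cells, now fibroblast-like) and to all the clusters now unnamed, except that rule 2 also left the one led by heart muscle genes unnamed. Rule 5 differed in the sub-clusters, where it called inflammatory a sub-cluster of 1471 Het bleomycin cells that the final rule left unnamed. Heart muscle markers were added after the clusters were seen, only to keep a cluster unnamed. The 3 unnamed clusters held 1164 cells.

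The 2 comparisons were these: WT bleomycin over WT PBS, and Het bleomycin over WT bleomycin. With groups of 1 library there was no test and no standard error. UMIs were summed per library and class and divided by the class total for CPM. Levels have exact 95% Poisson intervals, ratios exact conditional intervals and shares exact Clopper-Pearson intervals. A count of 0 was set to 3 UMIs for log2 ratios, the lower end of the exact interval is given as the bound of such a fold, and a class with under 50 cells in either library gave no gene value. A list value is the median log2 ratio of members with at least 20 UMIs in both libraries together, with 1000 Poisson resamples for its interval and 10000 random lists whose members were drawn from the 100 genes nearest in expression. The filters, the marker sets, the 21 gene lists, the comparisons and the rule for named genes were set before the data were examined. The lists are extracellular matrix, contractile, TGF-beta response, alveolar fibroblast, fibrosis-associated macrophage, inflammatory mediators, antigen presentation, transitional epithelium, activated AT2, p53 and senescence, surfactant and lipid synthesis, capillary endothelial, activated endothelial, BCAA (branched-chain amino acid) catabolism, amino acid transport and sensing, ATF4 amino acid response, glycolysis, oxidative phosphorylation, type I interferon response, cell division, and dissociation and heat shock. Older symbols not in the files, such as Ctgf, Cyr61 and Mut, were covered by their newer names, and Chil1 was left out. The contractile list was also meant for smooth muscle and pericyte, to which no cluster was given.

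Genes named in the text follow a rule. Bcat2, Bcat1 and Bckdk are always named. In fibroblast-, AT2-, alveolar macrophage-, monocyte-derived macrophage- and blood endothelial-like cells, the 2 genes with the highest and the 2 with the lowest ratio are named, among genes with at least 100 CPM and 50 UMIs in the library where they are higher and a CPM there at least 0.5 times that over all cells. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor genes, predicted genes, Xist, Y-linked genes and markers of other classes were left out of that step. For each list and class described, the members with the highest ratio, the lowest ratio and the highest mean CPM are named.

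Levels of free RNA were read as the CPM of genes of other cells in T-like and B-like cells. The intervals and lists were tested on simulated counts drawn from fibroblast-like sums, where intervals covered the true ratio for 95.8% and 96.3% of genes in the 2 comparisons. Of 100 unchanged lists 7 and 5 lay in the outer 5% of random lists, and a raised list of 20 genes lay at percentile 100. Alternatives fixed beforehand were a stricter filter (500 genes, 1000 UMIs, 10% mitochondrial), no filter, doublets kept, clustering resolutions 0.5 and 2.0, list genes kept among the variable genes, each cell classed by its own marker score, CPM without mitochondrial, ribosomal protein and haemoglobin genes, TMM scaling, cells thinned to 1000 UMIs, the mean of each cell's CPM, list members with at least 100 or 1 UMIs, and a second clustering at 1.0. Added after the data were seen were a common doublet threshold, leaving out the clusters led by Grem1 and by Hmga2, leaving out sub-clusters with Grem1 or Tnn among their leading genes, and the 5 naming rules set aside. The set of results treated as main answers there was widened after values had been seen.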

Results

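Single-cell 3' RNA libraries came from lungs of male mice, 1 library per group: wild type given PBS (WT PBS), wild type given bleomycin (WT bleomycin), and Bcat2 heterozygous given bleomycin (Het bleomycin). Bleomycin is a DNA-damaging drug that injures the lung and leads to scarring in rodents, and lungs were taken 14 days after it. The WT PBS, WT bleomycin and Het bleomycin libraries kept 9358, 7424 and 13553 cells, with medians of 7354, 5806 and 7910 UMIs and 2524, 2157 and 2720 genes per cell. The median mitochondrial share was 0.315%, 0.0598% and 0.263%. Wherever 3 values are given in a sequence, they follow this order of libraries.

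No group had replicates, so no test was made. Ranges in brackets are exact 95% intervals that cover counting error only, Poisson for UMIs and Clopper-Pearson for shares of cells. For a gene list, the value is the median log2 ratio of its members, with a 95% interval from Poisson resampling in square brackets. Its percentile is its place among 10000 random lists of equal size and like expression in the same libraries, a description of those libraries. A member counted as higher or lower differed by at least 1.5-fold. A name ending in "-like" is that of a cluster's best-scoring markers. Unnamed clusters held 3.75%, 5.47% and 3.003% of cells. They were led by club cell genes with haemoglobin genes, by heart muscle genes, and by macrophage genes with T cell genes.

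Bcat2, the mitochondrial enzyme that starts the breakdown of leucine, isoleucine and valine, was lower in the Het bleomycin library. Over all cells it stood at 17.5 (16.6 to 18.4), 19.1 (18.2 to 20.2) and 10.4 (9.82 to 10.9) UMIs per 1000000 (CPM), and Het bleomycin had 0.541 (0.503 to 0.583) times the level of WT bleomycin. The ratio was 0.533 (0.455 to 0.628) in fibroblast-like cells, 0.512 (0.446 to 0.587) in alveolar macrophage-like cells, 0.560 (0.450 to 0.695) in monocyte-derived macrophage-like cells and 0.635 (0.376 to 1.04) in blood endothelial-like cells. AT2-like cells held only 10 Bcat2 UMIs in WT bleomycin and 4 in Het bleomycin, a ratio of 0.646 (0.148 to 2.24). With cells thinned to 1000 UMIs the log2 ratio came to 2.09. Thinning leaves fewer UMIs still and a count of 0 is set to 3 UMIs, so that value gives no direction. WT bleomycin had 1.10 (1.02 to 1.18) times the Bcat2 of WT PBS, a log2 ratio of 0.13 that turned to -0.18 with every cell thinned to 1000 UMIs and to -0.021 with the mean of each cell's CPM. A 3' count reads the end of a transcript, and the labels do not say which part of Bcat2 is deleted, so this level does not check the genotype.

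**Figure D1:**
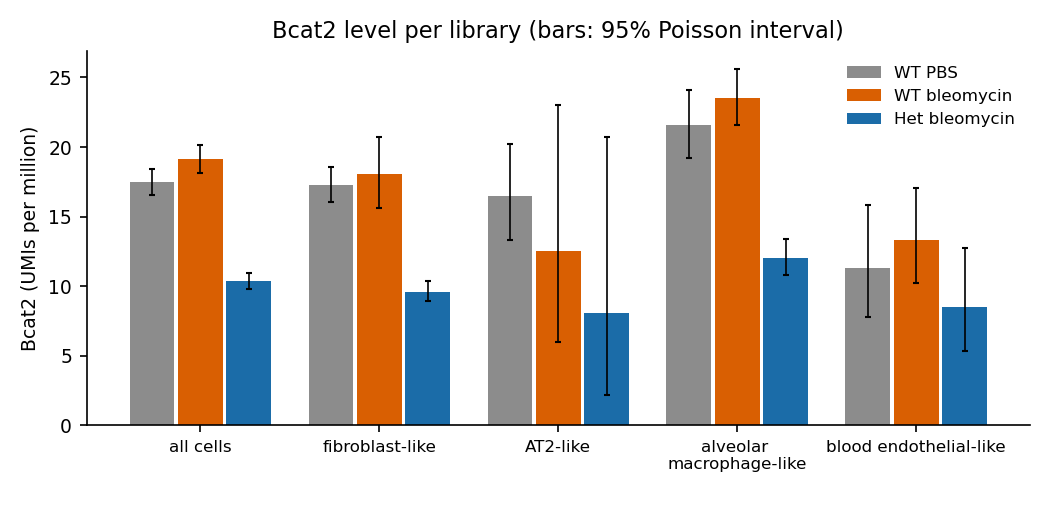
Bcat2 level in CPM for all cells and for fibroblast-like, AT2-like, alveolar macrophage-like and blood endothelial-like cells, by library. Bars span exact 95% Poisson intervals, and over all cells the levels were 17.5, 19.1 and 10.4 CPM.

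In WT bleomycin against WT PBS, fibroblast-like cells carried far more RNA of scar matrix genes, and less of genes that mark alveolar fibroblasts. Sparc, a collagen-binding matrix protein, stood 2.01-fold higher (1.997 to 2.03), and Inmt, a methyltransferase of alveolar fibroblasts, 4.86-fold lower (4.79 to 4.94). AT2-like cells, the surfactant makers, made up a share 6.07-fold lower (4.81 to 7.75), while the cluster scored as AT1-like, with genes of transitional epithelium among its leading genes, was 19.4-fold higher (13.2 to 29.8). In alveolar macrophage-like cells Arg1, which splits arginine into ornithine and urea, went from 4 UMIs to 2739, 430.2-fold higher (168 to 1580.1), and Spp1, the secreted phosphoprotein osteopontin, was 33.0-fold higher (31.8 to 34.2). Genes of cell division were higher in fibroblast-like cells, with a list median of 2.75.

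The mix of cells differed widely between these 2 libraries. Fibroblast-like cells were 47.7% of WT PBS and 18.3% of WT bleomycin, 2.61-fold lower (2.46 to 2.78). AT2-like cells stood at 6.63% (6.13 to 7.15) and 1.09% (0.867 to 1.35), and AT1-like cells at 0.289% (0.190 to 0.420) and 5.60% (5.09 to 6.15). The 10 leading genes of the AT1-like cluster held Ager, Cldn18 and Aqp5, found in AT1 cells, beside Cldn4, Krt7, Krt18 and Sfn, which are on the list of transitional epithelium. Its AT1 score of 2.80 lay close to its AT2 score of 2.70, so the name does not set AT1 cells apart from transitional cells. Club-like cells, 31, 110 and 35 in number, were 4.47-fold higher (2.98 to 6.90). The unnamed cluster led by club cell genes held more, 277, 132 and 245, so this fold need not hold for club cells. Mesothelial-like cells were 2.10-fold higher (1.76 to 2.51) and ciliated-like cells 1.47-fold lower (1.20 to 1.80). Lymphatic endothelial-like cells were 7.36-fold higher (5.74 to 9.55) and blood endothelial-like cells 1.69-fold higher (1.54 to 1.86). Monocyte-derived macrophage-like cells numbered 14 in WT PBS and 573 in WT bleomycin, 51.6-fold higher (30.5 to 94.97), and conventional dendritic-like cells were 4.36-fold higher (3.44 to 5.59). T-like cells were 1.65-fold higher (1.44 to 1.88), B-like cells 1.16-fold lower (0.990 to 1.35), and neutrophil-like cells 6.63-fold lower (4.37 to 10.5). Alveolar macrophage-like cells were 1.36-fold higher (1.252 to 1.48), but most of them lay in a cluster led by Krt79 and Fabp1 in WT PBS (1031 cells, with 4 from WT bleomycin) and in one led by Clec7a in WT bleomycin (837 cells, with 0 from WT PBS). A cluster that is mostly of 1 library can reflect that library rather than a cell type. With each cell classed by its own marker score instead, log2 ratios of shares were -1.94 for AT2-like, 2.999 for AT1-like and -2.04 for neutrophil-like cells. No cluster took the name smooth muscle, pericyte, classical monocyte or plasma, so no share is given for them. The unnamed cluster led by heart muscle genes, with 39, 133 and 108 cells, scored best for smooth muscle and had Myh11 and Cnn1, genes of smooth muscle contraction, among its leading genes.

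**Figure D2:**
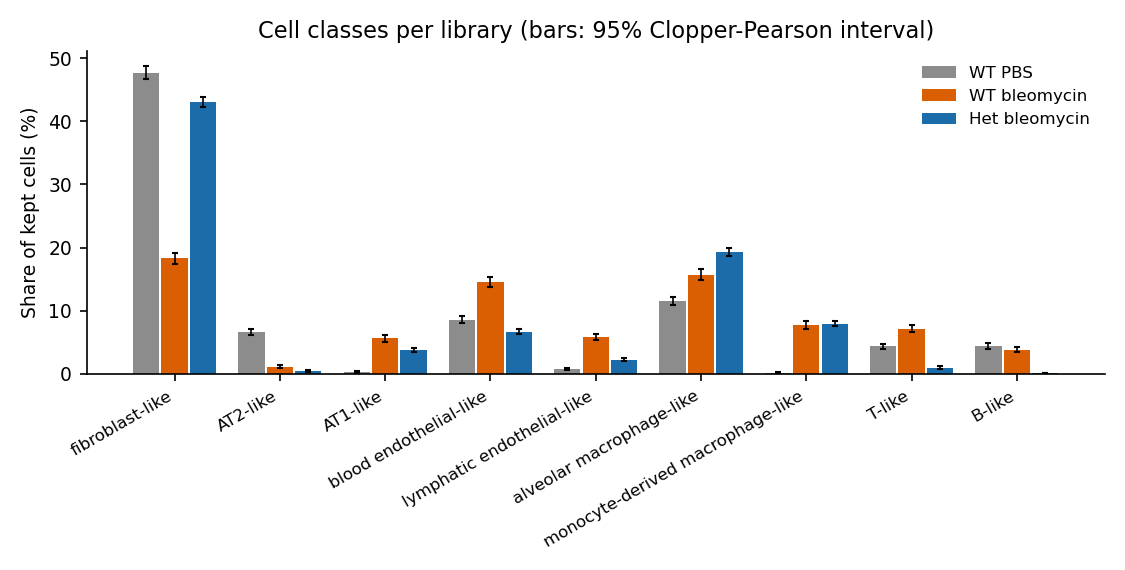
Share of kept cells in percent for 9 classes in the WT PBS, WT bleomycin and Het bleomycin libraries, with exact 95% Clopper-Pearson intervals as bars. Fibroblast-like cells made up 47.7%, 18.3% and 43.1%.

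In fibroblast-like cells, 26 of 30 extracellular matrix genes were higher in WT bleomycin and 0 lower (1.58 [1.55 to 1.61], percentile 100). Grem1, a secreted antagonist of bone morphogenetic proteins, went from 1 UMI to 1211 (0.0237 to 110.3 CPM), a ratio of 4654 (834 to 183985). Sparc went from 4728 to 9513 CPM, and Loxl1, an enzyme that cross-links elastin, was level at a ratio of 0.9754 (0.949 to 1.002). Spp1 stood 1037-fold higher (935 to 1154) in these cells (8.46 to 8776 CPM), beside 12.8, 834 and 2360.2 CPM in T-like cells of the 3 libraries, where it was read as free RNA. Free Col1a1, the main fibrillar collagen, was 430.2, 361 and 881 CPM in T-like cells. Of the contractile genes, 7 of 12 were higher and 1 lower (0.74 [0.53 to 0.77], percentile 99.99), from Tagln, an actin-binding protein of smooth muscle, at 4.33-fold higher (4.20 to 4.47) to Csrp1, the most expressed, at 1.84-fold lower (1.79 to 1.89). The TGF-beta response genes split, 4 higher and 4 lower of 14 (-0.056 [-0.10 to 0.014], percentile 22.9). Ccn2, a matricellular growth factor, was 3.36-fold higher (3.24 to 3.48), Bambi, a decoy receptor of the pathway, 2.92-fold lower (2.55 to 3.35), and Junb, the most expressed, 2.85-fold lower (2.79 to 2.92). Alveolar fibroblast genes were lower for 9 of 10 (-1.17 [-1.25 to -1.13], percentile 0), from the lipid droplet gene Plin2 at 1.18-fold lower (1.10 to 1.26) to Inmt, which was both lowest and most expressed (7941 to 1633 CPM). Gsta3, a glutathione transferase, was 5.83-fold lower (5.25 to 6.50). All 18 cell division genes were higher in fibroblast-like cells (2.75 [2.41 to 2.99], percentile 100), from Hmgb2, a chromatin protein and the most expressed, at 1.92-fold higher (1.77 to 2.07) to Cdk1, the kinase of mitotic entry, at 24.7-fold higher (15.9 to 40.2). Of the p53 and senescence genes, 6 of 14 were higher and 1 lower (0.54 [0.47 to 0.64], percentile 99.8), with Cdkn2a, an inhibitor of the cell cycle, 60.1-fold higher (29.6 to 142) and Cdkn1a, another and the most expressed, 1.61-fold lower (1.54 to 1.67). Inflammatory mediators were higher for 9 and lower for 4 of 18 (0.39 [0.17 to 0.79], percentile 97.9), with Saa3, an acute phase protein, 14.02-fold higher (13.2 to 14.9), Il6 2.45-fold lower (2.15 to 2.80) and Nfkbia, an inhibitor of NF-kappaB, 1.88-fold lower (1.82 to 1.94). Dissociation and heat shock genes of fibroblast-like cells were 0 higher and 17 lower of 20 (-1.14 [-1.19 to -1.10], percentile 0), with Hspa8 1.24-fold lower (1.21 to 1.26), Egr1 4.02-fold lower (3.92 to 4.13) and Fos, the most expressed, 2.26-fold lower (2.21 to 2.30).

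A second clustering split the fibroblast-like cells further. Alveolar fibroblast-like cells were 59.9%, 3.32% and 0.394% of fibroblast-like cells, inflammatory fibroblast-like cells 5.26%, 33.5% and 7.16%, adventitial fibroblast-like cells 16.6%, 14.001% and 13.8% and peribronchial fibroblast-like cells 5.08%, 3.91% and 8.20%. The last name covers different cells by library, since 223 of 227 in WT PBS were in a sub-cluster led by Hhip, a hedgehog-binding protein, and 43 of 53 in WT bleomycin and 464 of 479 in Het bleomycin in one led by S100b and Thbs2. Sub-clusters with no name held 13.2%, 45.2% and 70.5%. At resolution 1.0 peribronchial fibroblast-like cells were 5.06%, 1.77% and 1.35%, which turns the direction between the bleomycin libraries, and adventitial fibroblast-like cells 6.72%, 12.01% and 13.2%, which turns both that between the wild-type and that between the bleomycin libraries. Under naming rule 5 inflammatory fibroblast-like cells of Het bleomycin were 32.4%. The fibroblast-like share of WT bleomycin was lower still with each cell classed by its own marker score, 4.66-fold lower than in WT PBS. That choice gave log2 ratios of 7.35 for Grem1, 7.03 for Spp1, -1.44 for Inmt and -1.91 for Gsta3, and medians of -0.55 for alveolar fibroblast genes and 1.14 for cell division. The inflammatory median of fibroblast-like cells turned to -0.17.

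Alveolar macrophage-like cells of WT bleomycin had 13 of 20 fibrosis-associated macrophage genes higher and 1 lower (1.54 [1.37 to 1.74], percentile 100). Arg1 stood highest, Cd36, a scavenger receptor for lipids, was 5.76-fold lower (5.32 to 6.24), and Ctsd, a lysosomal protease and the most expressed, 1.51-fold higher (1.49 to 1.52). Spp1 went from 202 to 6656 CPM. Krt79, a keratin that marks alveolar macrophages, was 21.7-fold lower (20.4 to 23.2), and Fabp1, a fatty acid binding protein, 18.9-fold lower (17.4 to 20.6). Antigen presentation genes were higher for 8 of 11 and lower for 1 (1.68 [1.502 to 1.83], percentile 100), with the class II chain H2-Eb1 5.33-fold higher (5.14 to 5.52), the costimulator Cd80 2.27-fold lower (1.93 to 2.68) and the protease Ctss, the most expressed, 2.01-fold higher (1.98 to 2.03). Inflammatory mediators were higher for 4 and lower for 9 of 19 (-0.57 [-0.68 to -0.24], percentile 0.180). Saa3 was 5.26-fold higher (3.92 to 7.21), the cytokine Tnf 5.64-fold lower (4.72 to 6.78) and the chemokine Ccl6, the most expressed, 1.09-fold lower (1.08 to 1.10). Dissociation and heat shock genes, a sign of tissue handling, were in these cells 0 higher and 17 lower of 20 (-1.14 [-1.19 to -1.10], percentile 0), with Ier3 1.05-fold lower (0.997 to 1.10), Egr1 11.2-fold lower (10.5 to 12.1) and Hspa8, the most expressed, 1.35-fold lower (1.33 to 1.38). With 14 monocyte-derived macrophage-like cells in WT PBS, no gene value was taken for that class here. With each cell classed by its own marker score the alveolar macrophage-like share of WT bleomycin was lower than that of WT PBS, at a log2 ratio of -0.097, and at clustering resolution 0.5 the log2 ratio of the monocyte-derived share was 4.23. Arg1 had a log2 ratio of 7.01 with cells thinned to 1000 UMIs.

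The 81 AT2-like cells of WT bleomycin had 8 of 12 p53 and senescence genes higher (1.26 [0.82 to 1.47], percentile 100), with Gdf15, a stress-induced cytokine and the most expressed, 12.6-fold higher (10.5 to 15.1) and Sesn1, a p53 target, at 1.14-fold higher (0.520 to 2.23). Genes of activated AT2 cells were higher for 7 of 10 (0.91 [0.68 to 1.12], percentile 100), with Retnla, a secreted resistin-like protein, 187-fold higher (161 to 218), the calcium-binding S100g 1.10-fold higher (1.03 to 1.17) and Scd1, a fatty acid desaturase and the most expressed, 1.49-fold higher (1.43 to 1.54). Dmkn, a secreted epithelial protein, was 16.2-fold higher (12.8 to 20.8), Bex2 3.86-fold lower (2.97 to 5.13) and Bex4 2.93-fold lower (2.36 to 3.66). The transitional epithelium genes were mixed, 5 higher and 2 lower of 16 (0.31 [0.15 to 0.47], percentile 89.8), from Sfn, the epithelial 14-3-3 protein, at 6.80-fold higher (5.55 to 8.34) to the growth factor Mdk at 1.88-fold lower (0.879 to 4.82). S100a6, the most expressed, was 1.18-fold lower (1.07 to 1.31). Surfactant and lipid synthesis genes stayed near level, 2 higher and 1 lower of 17 (0.069 [-0.075 to 0.30], percentile 29.2), with Fasn, fatty acid synthase, 1.65-fold higher (1.51 to 1.81), the lipid regulator Srebf1 1.55-fold lower (1.10 to 2.25) and Scd1 as above. Inflammatory mediators (0.15 [-0.38 to 0.54], percentile 64.7) and antigen presentation genes (0.21 [0.092 to 0.36], percentile 79.0) had 4 of 14 and 1 of 8 members higher. In the former the chemokine Ccl9 was 9.11-fold higher (5.17 to 16.2), the cytokine Il6 6.81-fold lower (1.16 to 274) and Ccl6, the most expressed, 1.36-fold higher (1.19 to 1.54). In the latter Ctss was 3.46-fold higher (3.03 to 3.96), the class II regulator Ciita 1.24-fold lower (0.596 to 2.99) and Cd74, the most expressed, 1.10-fold lower (1.06 to 1.15). Free RNA of macrophage genes moved the same way, with 860.0, 2306 and 1337 CPM of the lysozyme gene Lyz2 in T-like cells. Ctss was 176, 535 and 413 CPM there and Ccl6 244, 320.0 and 319.6 CPM, against 119.5 to 414 CPM and 268 to 364 CPM in AT2-like cells from WT PBS to WT bleomycin. Dissociation and heat shock genes of AT2-like cells were 0 higher and 15 lower of 20 (-1.10 [-1.24 to -0.88], percentile 0), with Hspa1b 1.46-fold higher (0.839 to 2.41), Egr1 9.14-fold lower (6.69 to 12.8) and Hspa8, the most expressed, 1.06-fold lower (0.976 to 1.16). Free Sftpc, the surfactant protein that marks AT2 cells, was 2571, 226 and 154 CPM in T-like cells. Under each cell's own marker score the transitional epithelium median was 2.33, and under a stricter filter that of p53 and senescence genes was 0.58. With the mean of each cell's CPM the inflammatory median was 0.84, and the log2 ratio of Retnla 6.10 and of Dmkn 3.20, while that of Dmkn was 2.06 with cells thinned to 1000 UMIs.

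Blood endothelial-like cells of WT bleomycin had 9 of 16 activated endothelial genes higher and 1 lower (0.72 [0.64 to 0.90], percentile 100). Ackr1, a venular chemokine receptor counted with 2 UMIs in WT PBS, had a ratio of 137 (37.6 to 1131). The basement membrane collagen Col4a1, the most expressed, was 3.07-fold higher (2.92 to 3.23), and the leukocyte adhesion molecule Vcam1 2.29-fold lower (1.84 to 2.84). Lrg1, a secreted glycoprotein that promotes vessel growth, was 10.01-fold higher (8.96 to 11.2) and Ankrd37, a hypoxia-induced gene, 22.8-fold higher (14.7 to 37.6). Cyp1a1, the cytochrome P450 induced through the aryl hydrocarbon receptor, was 38.5-fold lower (23.1 to 69.6). Of 16 capillary genes 0 were higher and 7 lower (-0.41 [-0.52 to -0.34], percentile 0.0800), from the receptor Kit at 1.37-fold higher (1.22 to 1.53) to the cytochrome Cyp4b1 at 3.26-fold lower (3.05 to 3.48). Gpihbp1, the capillary anchor of lipoprotein lipase and the most expressed, was 1.12-fold lower (1.07 to 1.18). Myl7, a heart atrial muscle gene, was 17.8-fold lower (11.96 to 27.4), which came to a log2 ratio of 0.015 with each cell classed by its own marker score. Dissociation and heat shock genes of blood endothelial-like cells were 0 higher and 7 lower of 20 (-0.53 [-0.59 to -0.46], percentile 0), with Hsph1 1.21-fold higher (0.952 to 1.54), Egr1 3.397-fold lower (3.12 to 3.70) and Jun, the most expressed, 1.37-fold lower (1.32 to 1.43).

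Type I interferon response genes were higher in WT bleomycin over all cells, 10 of 18 (0.89 [0.82 to 0.91], percentile 100). Oas1a, an antiviral enzyme, was 9.43-fold higher (7.998 to 11.2), and Ifitm3, a membrane protein that blocks virus entry and both the lowest and most expressed, 1.97-fold lower (1.95 to 1.99). In AT2-like cells 6 of 10 were higher (0.90 [0.43 to 1.27], percentile 99.99), from Isg15, a ubiquitin-like protein, at 5.17-fold higher (2.84 to 9.27) to Ifitm3, the most expressed, at 1.49-fold lower (1.31 to 1.71). That median turned to -1.04 with cells thinned to 1000 UMIs and was 0.19 with members of at least 100 UMIs. Blood endothelial-like cells had 3 higher and 3 lower of 17 (0.018 [-0.19 to 0.15], percentile 60.1), from Oas1a at 1.94-fold higher (1.08 to 3.64) to Ifit1 at 1.92-fold lower (1.36 to 2.72), with Ifitm3 the most expressed at 1.10-fold higher (1.07 to 1.13). In fibroblast-like cells 11 of 18 were higher (0.91 [0.77 to 1.07], percentile 100), with Mx1, an antiviral GTPase, 14.5-fold higher (7.74 to 29.1) and Ifitm3, the most expressed, 1.36-fold lower (1.34 to 1.38). In alveolar macrophage-like cells 16 were higher and 1 lower (1.63 [1.496 to 1.91], percentile 100), where the antiviral enzyme Rsad2 was 7.07-fold higher (3.92 to 14.02), Ifi27l2a, the most expressed, 6.60-fold higher (6.22 to 7.003) and Ifitm3 2.20-fold lower (2.11 to 2.30). Cell division genes were higher for 18 of 18 over all cells (1.71 [1.63 to 1.82], percentile 100), 12 of 18 in alveolar macrophage-like cells (0.94 [0.77 to 1.01], percentile 100) and 11 of 16 in blood endothelial-like cells (1.29 [0.88 to 1.64], percentile 100). Over all cells Ccnb1, a mitotic cyclin, was 4.92-fold higher (4.14 to 5.89) and Hmgb2, the lowest and most expressed, 1.95-fold higher (1.90 to 1.999). In alveolar macrophage-like cells Ccnb1 was 3.56-fold higher (2.71 to 4.74), the replication helicase subunit Mcm5 1.04-fold higher (0.874 to 1.23) and Hmgb2, the most expressed, 1.23-fold higher (1.17 to 1.30). In blood endothelial-like cells the cyclin Ccna2 was 16.1-fold higher (2.65 to 660.1), Tyms, which makes thymidylate, 1.06-fold higher (0.739 to 1.52) and Hmgb2, the most expressed, 1.45-fold higher (1.254 to 1.69), and the list median was 0.47 with members of at least 100 UMIs. Of 25 genes of branched-chain amino acid breakdown over all cells, 1 was higher and 3 lower (-0.19 [-0.24 to -0.13], percentile 4.91). Bcat1, the cytosolic partner of Bcat2, was 6.74-fold higher (3.73 to 13.2) over all cells, a log2 ratio of 3.50 with cells thinned to 1000 UMIs, and 24.2-fold higher (12.3 to 52.9) in fibroblast-like cells. Aldh6a1, an enzyme of valine breakdown, was 2.53-fold lower (2.29 to 2.79), Acadsb, of isoleucine breakdown and the most expressed, 2.30-fold lower (2.20 to 2.40), and Bckdk, the kinase that holds the next enzyme complex inactive, 1.03-fold higher (0.969 to 1.09). Dissociation and heat shock genes were lower for 18 of 20 over all cells (-1.07 [-1.10 to -1.04], percentile 0), from the chaperone Hspa8 at 1.04-fold higher (1.04 to 1.05) to the immediate early gene Egr1 at 7.61-fold lower (7.48 to 7.75). Junb, the most expressed of them, was 1.97-fold lower (1.95 to 1.99), and it is also on the list of TGF-beta response.

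**Figure D3:**
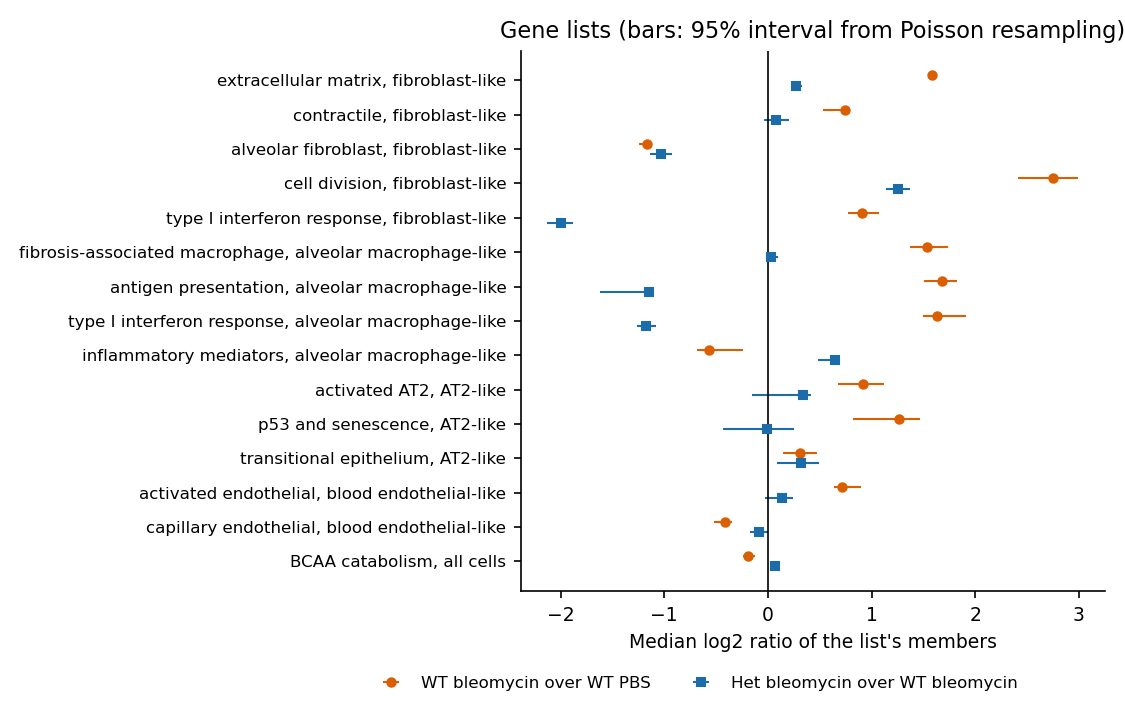
Median log2 ratio of CPM over the members of each gene list in the class named, for WT bleomycin over WT PBS and for Het bleomycin over WT bleomycin, with 95% intervals from Poisson resampling as bars. For extracellular matrix genes in fibroblast-like cells the medians were 1.58 and 0.27.

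In Het bleomycin against WT bleomycin, genes of the type I interferon response were lower, with log2 medians from -1.997 in fibroblast-like cells to -0.51 in AT2-like cells. In fibroblast-like cells Mx1 was 26.6-fold lower. Class II antigen presentation genes were lower in macrophage-like cells, H2-Eb1 by 4.22-fold in alveolar macrophage-like cells. Scar matrix genes of fibroblast-like cells had a median of 0.27 with CPM, where 5 of 30 were higher and 3 lower, and of 0.65 with TMM scaling. Alveolar fibroblast genes were again lower in these cells, with Inmt 4.83-fold lower (4.74 to 4.93). B-like cells were 34.4-fold lower (20.5 to 62.4), T-like cells 7.17-fold lower (5.92 to 8.72) and fibroblast-like cells 2.36-fold higher (2.22 to 2.502).

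The Het bleomycin library had 43.1% (42.2 to 43.9) fibroblast-like cells against 18.3% (17.4 to 19.2) in WT bleomycin. Most of that gap lay in a cluster led by Grem1, Spp1 and Timp1, the last an inhibitor of matrix proteases, with 1, 264 and 2883 cells, and in one led by Hmga2, a chromatin protein of growing tissue, with 1, 10 and 392. Without these clusters fibroblast-like cells were 47.7%, 14.6% and 18.9%, and Het bleomycin stood 1.30-fold higher (1.21 to 1.39). Under the earliest 2 naming rules the Het share stood 1.11-fold higher, and 1.42-fold higher with each cell classed by its own marker score. AT2-like cells were 2.59-fold lower (1.83 to 3.71), at 57 cells, a log2 ratio that moved to -0.39 under each cell's own score, -0.78 under a stricter filter and -0.77 at clustering resolution 2.0. AT1-like cells were 1.47-fold lower (1.29 to 1.67), though under each cell's own score they were higher, at a log2 ratio of 0.12. Club-like cells were 5.74-fold lower (3.89 to 8.65), leaving out the unnamed cluster led by club cell genes (132 WT and 245 Het bleomycin cells). Ciliated-like cells were 1.76-fold higher (1.47 to 2.13). Blood endothelial-like cells were 2.17-fold lower (1.99 to 2.38) and lymphatic endothelial-like cells 2.56-fold lower (2.21 to 2.97). Among leukocytes, NK-like cells were 18.3-fold lower (7.32 to 58.7), or at a log2 ratio of -2.23 under each cell's own score, nonclassical monocyte-like cells 5.87-fold lower (3.803 to 9.32), conventional dendritic-like cells 3.35-fold lower (2.76 to 4.06) and neutrophil-like cells 3.79-fold higher (2.48 to 6.02). Alveolar macrophage-like cells were 1.23-fold higher (1.14 to 1.31), most of them in a cluster led by Chil3 and Marco that held 2056 cells of Het bleomycin and 88 of WT bleomycin. Monocyte-derived macrophage-like cells had a ratio of 1.03 (0.930 to 1.14). A cluster of 3, 16 and 208 erythroid-like cells was led by haemoglobin genes together with Cfd and Car3, genes of fat tissue.

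Interferon response genes were lower in Het bleomycin for 15 of 18 over all cells (-1.37 [-1.46 to -1.27], percentile 0), from Ifitm3, the most expressed, at 1.39-fold higher (1.38 to 1.40) to Mx1 at 6.10-fold lower (4.54 to 8.31). In fibroblast-like cells 16 of 18 were lower (-1.997 [-2.13 to -1.88], percentile 0), from Ifitm3, the most expressed, at 1.09-fold lower (1.08 to 1.11) to Mx1 at 26.6-fold lower (13.97 to 55.0), with Ifi27l2a 5.43-fold lower (5.26 to 5.62). In alveolar macrophage-like cells 15 of 18 were lower (-1.17 [-1.27 to -1.08], percentile 0), Ifi27l2a being lowest and most expressed at 5.54-fold lower (5.33 to 5.77) and Ifitm3 highest at 1.15-fold lower (1.10 to 1.20). Monocyte-derived macrophage-like cells had 15 lower (-1.63 [-1.73 to -1.38], percentile 0), with Ifit1 at 1.04-fold lower (0.659 to 1.66), Mx1 5.36-fold lower (2.19 to 15.7) and Ifi27l2a 3.22-fold lower (3.04 to 3.399). In blood endothelial-like cells 12 of 17 were lower (-1.005 [-1.20 to -0.83], percentile 0), with Ifit1 at 1.02-fold lower (0.669 to 1.58), Zbp1, a sensor of viral nucleic acid, 11.3-fold lower (4.67 to 35.5) and Ifitm3, the most expressed, 1.11-fold lower (1.08 to 1.14). In AT2-like cells 1 was higher and 3 lower of 7 (-0.51 [-1.23 to -0.12], percentile 1.71), with the signal transducer Stat2 1.94-fold higher (0.768 to 5.01), Ifi27l2a 3.92-fold lower (2.12 to 7.92) and Ifitm3, the most expressed, 1.43-fold lower (1.13 to 1.81). With each cell classed by its own score the fibroblast-like median was -0.83, and without the clusters led by Grem1 and by Hmga2 it was -1.40.

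Antigen presentation genes were lower in Het bleomycin for 8 of 11 in alveolar macrophage-like cells (-1.14 [-1.62 to -1.11], percentile 0), from Ctss, the most expressed, at 1.08-fold higher (1.07 to 1.08) to H2-Eb1 at 4.22-fold lower (4.12 to 4.32). These cells lay mostly in different clusters in the bleomycin libraries, and no value within a cluster was computed. Monocyte-derived macrophage-like cells had 8 of 11 lower (-1.17 [-1.37 to -1.06], percentile 0), from Cd80 at 1.44-fold higher (1.10 to 1.88) to the class II chain H2-Ab1 at 3.04-fold lower (2.99 to 3.10), with Ctss, the most expressed, 1.04-fold lower (1.03 to 1.05). In AT2-like cells 5 of 7 were lower (-1.23 [-1.36 to -0.98], percentile 0), with H2-DMb1 1.33-fold lower (0.957 to 1.86), H2-Eb1 2.71-fold lower (2.17 to 3.42) and the invariant chain Cd74, the most expressed, 1.41-fold lower (1.32 to 1.51). In alveolar macrophage-like cells Cd74, which lies outside the H2 region, was 3.57-fold lower (3.53 to 3.61). Other genes of this library, chosen after their values were seen, also stood apart over all cells: the olfactory receptor gene Or2n1c was 0, 0 and 24.3 CPM, and the H2 region genes H2-Q7 and H2-Q6 were 18.3, 53.3 and 3.51 and 16.0, 34.0 and 3.16 CPM. The labels call all mice C57BL/6, and how the heterozygous line was made was not given in the sources used here. The AT2-like median was -0.34 with each cell classed by its own score and -0.28 under a stricter filter.

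Fibroblast-like cells of Het bleomycin had 5 of 30 matrix genes higher and 3 lower (0.27 [0.26 to 0.33], percentile 99.8). Postn, a matrix protein of wound repair, was 2.38-fold higher (2.26 to 2.51), the collagen Col8a1 was 3.20-fold lower (2.99 to 3.42) and Sparc 1.29-fold higher (1.28 to 1.29). Tnn, tenascin-W, an extracellular matrix glycoprotein, was 33.2-fold higher (24.2 to 46.7), from 3.55 to 118 CPM, and the B cell chemokine Cxcl13 6.30-fold higher (5.57 to 7.16). Contractile genes were higher for 3 and lower for 0 of 12 (0.079 [-0.039 to 0.20], percentile 64.3), with the smooth muscle actin Acta2 1.99-fold higher (1.94 to 2.05), Csrp1 1.27-fold lower (1.24 to 1.31) and Cald1, an actin-binding protein and the most expressed, 1.11-fold higher (1.08 to 1.13). TGF-beta response genes were higher for 2 and lower for 1 of 14 (-0.047 [-0.10 to 0.061], percentile 44.7). The ligand Tgfb1 was 2.25-fold lower (2.05 to 2.46) and Pmepa1, the most expressed, 1.19-fold lower (1.17 to 1.22). Alveolar fibroblast genes were lower for 6 of 10 (-1.03 [-1.13 to -0.92], percentile 0), from Gpm6b at 1.13-fold lower (1.08 to 1.19) to the amino acid transporter Slc7a10 at 8.87-fold lower (5.75 to 13.8), with Inmt the most expressed. Cell division genes were higher for all 18 (1.26 [1.14 to 1.37], percentile 100), with Ccnb1 3.55-fold higher (2.69 to 4.76), Tyms 1.52-fold higher (1.32 to 1.76) and Hmgb2, the most expressed, 2.08-fold higher (1.95 to 2.23). That median was 0.29 without the clusters led by Grem1 and by Hmga2 and 0.13 with each cell classed by its own score. Over all cells, cell division genes were near level (0.079 [0.042 to 0.13], percentile 57.8), from the spindle gene Tpx2 at 1.43-fold higher (1.33 to 1.52) to Mcm5 at 1.36-fold lower (1.26 to 1.48), with Hmgb2 the most expressed at 1.33-fold lower (1.31 to 1.36). In blood endothelial-like cells 0 were higher and 7 lower of 16 (-0.37 [-0.65 to -0.16], percentile 0.290), with Cdk1 1.16-fold higher (0.678 to 1.96), the replication factor Pclaf 2.30-fold lower (1.36 to 4.09) and Hmgb2 1.11-fold lower (0.964 to 1.27). Alveolar macrophage-like cells had 0 higher and 1 lower of 18 (-0.25 [-0.32 to -0.19], percentile 0.0300), with the kinetochore gene Cenpf 1.26-fold higher (1.10 to 1.44), Mcm5 1.67-fold lower (1.43 to 1.96) and Hmgb2 1.05-fold higher (1.01 to 1.10). Monocyte-derived macrophage-like cells had 0 higher and 7 lower of 18 (-0.25 [-0.42 to -0.11], percentile 1.73), with Rrm2, which makes deoxynucleotides, 1.43-fold higher (0.871 to 2.40), the spindle gene Nusap1 6.35-fold lower (3.58 to 12.1) and Hmgb2 1.21-fold lower (1.10 to 1.32). With cells thinned to 1000 UMIs the medians of these macrophage classes turned to 0.073 and 0.54, and that of the monocyte-derived class to 0.33 with the mean of each cell's CPM and 0.057 at clustering resolution 2.0. Without the clusters led by Grem1 and by Hmga2 the log2 ratio was 3.62 for Tnn, 3.65 for Cxcl13, -1.72 for Ifi27l2a and -1.33 for Inmt. Of the p53 and senescence genes 0 were higher and 1 lower (-0.18 [-0.24 to -0.056], percentile 29.6), from Bbc3 at 1.249-fold higher (1.01 to 1.55) to Gdf15 at 1.68-fold lower (1.46 to 1.93), with Cdkn1a the most expressed at 1.001-fold lower (0.962 to 1.04). Inflammatory mediators were higher for 2 and lower for 8 of 19 (-0.37 [-0.61 to -0.23], percentile 8.63), from Cxcl3 at 2.30-fold higher (0.583 to 19.9) to Cxcl10 at 3.39-fold lower (3.04 to 3.76), with Saa3 the most expressed at 1.29-fold lower (1.26 to 1.33). The median of all genes in fibroblast-like cells, Het over WT bleomycin, was -0.15 with CPM and 0.23 with TMM factors, which set libraries level by their shared genes, so list medians shift by that much with the scaling. Over WT PBS the median of all genes was 0.090 with CPM and -0.13 with TMM in fibroblast-like cells, 0.11 and -0.13 in AT2-like cells, and -0.15 and 0.070 in alveolar macrophage-like cells.

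Alveolar macrophage-like cells of Het bleomycin had 10 of 19 inflammatory mediators higher and 1 lower (0.65 [0.49 to 0.69], percentile 100), with the neutrophil chemokine Cxcl3 3.30-fold higher (1.93 to 5.97), the interferon-induced chemokine Cxcl10 3.29-fold lower (2.61 to 4.16) and Ccl6 at 1.11-fold higher (1.10 to 1.12). In the same cells dissociation and heat shock genes were 0 higher and 0 lower of 20 (0.23 [0.19 to 0.27], percentile 99.03), with Ier3 1.48-fold higher (1.43 to 1.54), Hspa1b 1.35-fold lower (0.989 to 1.84) and Hspa8, the most expressed, 1.02-fold lower (1.004 to 1.04). Monocyte-derived macrophage-like cells had 7 higher and 2 lower (0.37 [0.30 to 0.51], percentile 100), with Cxcl3 3.17-fold higher (2.48 to 4.07), the receptor antagonist Il1rn 1.63-fold lower (1.52 to 1.74) and Ccl6 1.23-fold lower (1.22 to 1.248). Fibrosis-associated macrophage genes were higher for 6 and lower for 4 of 20 in alveolar macrophage-like cells (0.033 [-0.012 to 0.10], percentile 72.1). Arg1 was 3.60-fold higher (3.45 to 3.75) there, the growth factor Pdgfb 2.95-fold lower (2.41 to 3.63) and Spp1 1.80-fold higher (1.79 to 1.81). In monocyte-derived macrophage-like cells 5 were higher and 1 lower (0.031 [-0.046 to 0.066], percentile 63.6), with Arg1 6.01-fold higher (5.72 to 6.31), Igf1, insulin-like growth factor, 1.54-fold lower (1.46 to 1.64) and Spp1 1.60-fold higher (1.59 to 1.62). Free Spp1 in T-like cells, 834 CPM in WT bleomycin and 2360.2 CPM in Het bleomycin, was higher in the same direction. Ecm1, a secreted matrix protein, was 5.77-fold higher (5.48 to 6.09) in alveolar and 3.77-fold higher (3.62 to 3.93) in monocyte-derived macrophage-like cells, and Marco, a scavenger receptor, 4.15-fold higher (3.997 to 4.31) in the former. With list genes kept among the variable genes the log2 ratio of Ecm1 in alveolar macrophage-like cells was 1.88. H2-M2, a class I-like histocompatibility gene, was 7.43-fold lower (6.51 to 8.50) in monocyte-derived macrophage-like cells.

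In AT2-like cells of Het bleomycin, surfactant and lipid synthesis genes were higher for 6 of 17 and lower for 0 (0.46 [0.29 to 0.58], percentile 99.1). Insig1, a brake on sterol synthesis, was 1.43-fold lower (0.723 to 2.98) and Scd1, the most expressed, 1.47-fold higher (1.40 to 1.55). Transitional epithelium genes were higher for 6 and lower for 3 of 14 (0.31 [0.085 to 0.49], percentile 88.3), a median that turned to -0.18 with the mean of each cell's CPM. The growth factor Areg was 3.03-fold higher (1.94 to 4.81), S100a6 1.77-fold higher (1.55 to 2.02), and Plaur, the urokinase receptor, had 4 UMIs in Het bleomycin, 6.81-fold lower (2.48 to 26.1). Activated AT2 genes were higher for 2 and lower for 3 of 11 (0.34 [-0.16 to 0.42], percentile 99.1), with the acute phase gene Orm1, counted with 3 UMIs in WT bleomycin, at a ratio of 10.2 (3.01 to 54.0) and Retnla 2.63-fold lower (2.46 to 2.81), and the median turned to -0.27 with each cell classed by its own score. The p53 and senescence genes were higher for 2 and lower for 3 of 10 (-0.013 [-0.43 to 0.25], percentile 17.7), with Cdkn1a, the most expressed, 2.06-fold higher (1.72 to 2.48). Gdf15 was 8.64-fold lower (5.71 to 13.7), but under a stricter filter it was higher, at a log2 ratio of 1.91, and with list genes kept among the variable genes at 1.97. Neat1, a nuclear noncoding RNA, was 4.21-fold higher (3.52 to 5.05) and Dmkn 6.42-fold lower (4.14 to 10.4), at log2 ratios of 1.20 and -1.02 with each cell classed by its own score. With cells thinned to 1000 UMIs Dmkn was near level, at -0.078. Ythdf2, a reader of methylated RNA, was 4.67-fold higher (2.69 to 8.48), turning to a log2 ratio of -0.078 with cells thinned to 1000 UMIs. Of 6 inflammatory mediators 1 was higher (-0.11 [-0.36 to 0.37], percentile 9.13), the cytokine Il1b at 3.14-fold higher (1.73 to 5.89), and Ccl6, the lowest and most expressed, was 1.19-fold lower (0.977 to 1.46). That median turned to 0.51 under a stricter filter.

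Blood endothelial-like cells of Het bleomycin had 4 of 16 activated endothelial genes higher and 2 lower (0.14 [-0.031 to 0.25], percentile 95.05), with the vasoconstrictor Edn1 1.80-fold higher (1.68 to 1.93), Esm1, a proteoglycan of sprouting vessels, 2.76-fold lower (1.78 to 4.43) and Col4a1 1.46-fold lower (1.40 to 1.52). Capillary genes were higher for 1 and lower for 3 of 16 (-0.090 [-0.17 to -0.0038], percentile 20.1), with Gpihbp1, the highest and most expressed, 1.59-fold higher (1.53 to 1.66) and Aplnr, the apelin receptor, 2.97-fold lower (2.25 to 3.98). Cfd, complement factor D, went from 0 to 725 UMIs, at least 341-fold higher, and Lcn2, which binds iron-carrying siderophores, was 7.27-fold higher (5.88 to 9.05), with log2 ratios of 4.13 and 2.07 when cells were thinned to 1000 UMIs. Of some genes known from fat tissue, chosen after their values were seen and not as a fixed list, Fabp4 stood at 62.2 and 84.0 CPM in these cells, Adipoq went from 0 to 27 UMIs, Retn from 0 to 56 and Car3 from 1 to 7. H2-Q7, a nonclassical histocompatibility gene, was 4.34-fold lower (3.57 to 5.31) and Nkain2 3.58-fold lower (3.16 to 4.07). Genes of branched-chain amino acid breakdown over all cells were higher for 1 and lower for 1 of 25 (0.072 [0.030 to 0.10], percentile 68.6). Bcat1 was 4.01-fold higher (3.18 to 5.13) over all cells, a log2 ratio of 1.002 with the mean of each cell's CPM, and 1.35-fold higher (1.04 to 1.77) in fibroblast-like cells, Bcat2 the lowest, and Hsd17b10, of isoleucine breakdown and the most expressed, 1.05-fold higher (1.01 to 1.09). Bckdk was 1.06-fold higher (1.003 to 1.12). Dissociation and heat shock genes were near level over all cells (0.061 [0.045 to 0.086], percentile 69.7), with Egr1 1.56-fold higher (1.53 to 1.59), Junb 1.248-fold lower (1.24 to 1.26) and Hspa8, the most expressed, 1.15-fold lower (1.14 to 1.16).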

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

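No paired analysis was possible because each group holds 1 library and no result comes from a test. Results were computed again with 1 choice changed at a time, where the choice applies to them. The earlier naming rules were run only for the fibroblast-like share and matrix list, and rule 5 for its states, so other fibroblast-like values under them are not known. For the results that answer a comparison, 411 of 540 alternative values stayed within the counting interval of the reported value, 124 left it and 5 changed direction from an interval that excluded 0. Counting also those whose interval held 0 or which stayed inside it, 11 of them changed sign. For other lists and named genes the counts were 1716, 361 and 36 of 2113, with 121 changes of sign. CPM without mitochondrial, ribosomal protein and haemoglobin genes moved none of the former. Values are log2 ratios of shares, log2 ratios of genes or list medians, with the reported value in brackets where the sign changed, and the cause was not tested. Classes with few cells limit the AT2-like values, with 81 and 57 cells in the bleomycin libraries, and monocyte-derived macrophage-like cells gave no value over WT PBS.

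Among alternatives fixed before the data were examined, these values changed. Classing each cell by its own marker score gave, over WT PBS, for shares fibroblast-like -2.22, AT2-like -1.94, alveolar macrophage-like -0.097 (from 0.44), AT1-like 2.999, neutrophil-like -2.04 and T-like 0.93. Also over WT PBS, this setting gave, in fibroblast-like matrix 1.11, alveolar fibroblast -0.55, inflammatory -0.17 (from 0.39), glycolysis -0.074 (from 0.19) and cell division 1.14. It gave as well, over WT PBS, in AT2-like transitional 2.33, and in alveolar macrophage-like interferon 1.17, and in blood endothelial-like Myl7 0.015 (from -4.15). Classing each cell by its own marker score gave, over WT bleomycin, for shares fibroblast-like 0.50, AT2-like -0.39, alveolar macrophage-like 0.52, AT1-like 0.12 (from -0.55), ciliated-like 1.15, conventional dendritic-like -1.16 and NK-like -2.23. Other values over WT bleomycin were, in fibroblast-like matrix 0.36, alveolar fibroblast -0.76, BCAA 0.050 (from -0.10), oxidative phosphorylation -0.087 (from 0.077), interferon -0.83 and cell division 0.13. Further values over WT bleomycin were, in alveolar macrophage-like interferon -0.86. TMM scaling gave, over WT PBS, in fibroblast-like matrix 1.36, alveolar fibroblast -1.38, glycolysis -0.030 (from 0.19), oxidative phosphorylation -0.055 (from 0.16) and interferon 0.69. Also over WT PBS, this setting gave, in alveolar macrophage-like fibrosis-associated 1.76, antigen presentation 1.90 and BCAA 0.069 (from -0.15), and in AT2-like antigen presentation -0.020 (from 0.21) and transitional 0.083. TMM scaling gave, over WT bleomycin, in all cells Bcat2 -0.76, BCAA 0.20 and glycolysis 0.027 (from -0.099). It gave as well, over WT bleomycin, in fibroblast-like matrix 0.65, alveolar fibroblast -0.66, inflammatory 0.0064 (from -0.37), p53 0.20 (from -0.18), BCAA 0.28 (from -0.10), interferon -1.62, cell division 1.63 and dissociation 0.16 (from -0.22). Other values over WT bleomycin were, in alveolar macrophage-like antigen presentation -1.10. Thinning cells to 1000 UMIs gave, over WT PBS, in all cells Bcat2 -0.18 (from 0.13), and in fibroblast-like matrix 1.34, alveolar fibroblast -0.96, oxidative phosphorylation -0.0019 (from 0.16) and cell division 1.19. Further values over WT PBS were, in AT2-like transitional 0.64 and interferon -1.04 (from 0.90), and in alveolar macrophage-like interferon 1.14. Thinning cells to 1000 UMIs gave, over WT bleomycin, in all cells Bcat2 -0.55, glycolysis 0.042 (from -0.099) and dissociation -0.024 (from 0.061), and in fibroblast-like matrix 0.51 and interferon -1.59. Also over WT bleomycin, this setting gave, in alveolar macrophage-like fibrosis-associated -0.019 (from 0.033), antigen presentation -1.06, interferon -0.98 and cell division 0.073 (from -0.25). It gave as well, over WT bleomycin, in AT2-like transitional 0.017 and Ythdf2 -0.078 (from 2.22), and in blood endothelial-like capillary 0.017 (from -0.090), and in monocyte-derived macrophage-like cell division 0.54 (from -0.25). The mean of each cell's CPM gave, over WT PBS, in all cells Bcat2 -0.021 (from 0.13) and BCAA -0.057, and in fibroblast-like matrix 1.41, alveolar fibroblast -0.96 and cell division 1.64. Other values over WT PBS were, in alveolar macrophage-like antigen presentation 1.45 and interferon 1.47, and in AT2-like transitional 0.69. This setting gave, over WT bleomycin, in all cells Bcat2 -0.67, BCAA 0.12, glycolysis 0.011 (from -0.099) and dissociation -0.040 (from 0.061). Further values over WT bleomycin were, in fibroblast-like matrix 0.53, interferon -1.62 and cell division 1.37, and in alveolar macrophage-like fibrosis-associated -0.013 (from 0.033) and antigen presentation -1.09. Also over WT bleomycin, this setting gave, in AT2-like transitional -0.18 (from 0.31), amino acid transport -0.058 (from 0.35) and dissociation -0.012 (from 0.34), and in monocyte-derived macrophage-like cell division 0.33 (from -0.25). A stricter filter gave, over WT PBS, for shares alveolar macrophage-like 0.57. A stricter filter gave, over WT bleomycin, for shares AT2-like -0.78, alveolar macrophage-like 0.10 and monocyte-derived macrophage-like 0.49, and in alveolar macrophage-like antigen presentation -1.10, and in monocyte-derived macrophage-like dissociation -0.034 (from 0.19). It gave as well, over WT bleomycin, in AT2-like Gdf15 1.91 (from -3.11). No filter on cells gave, over WT PBS, for shares alveolar macrophage-like 0.58. No filter on cells gave, over WT bleomycin, for shares AT2-like -0.81, alveolar macrophage-like 0.19 and monocyte-derived macrophage-like 0.30, and in alveolar macrophage-like fibrosis-associated -0.034 (from 0.033). Keeping doublet calls gave, over WT PBS, for shares fibroblast-like -1.48. Keeping doublet calls gave, over WT bleomycin, for shares AT2-like -0.80 and monocyte-derived macrophage-like 0.36. Clustering at resolution 0.5 gave, over WT PBS, for shares alveolar macrophage-like 0.28, monocyte-derived macrophage-like 4.23 and ciliated-like -0.95. This setting gave, over WT bleomycin, for shares alveolar macrophage-like 0.41, monocyte-derived macrophage-like -0.32 (from 0.043) and ciliated-like 1.19. Clustering at resolution 2.0 gave, over WT bleomycin, for shares AT2-like -0.77, and in monocyte-derived macrophage-like cell division 0.057 (from -0.25). Keeping list genes among the variable genes gave, over WT PBS, for shares alveolar macrophage-like 0.58. Keeping list genes among the variable genes gave, over WT bleomycin, for shares alveolar macrophage-like 0.072 and monocyte-derived macrophage-like 0.57, and in alveolar macrophage-like fibrosis-associated -0.026 (from 0.033) and antigen presentation -1.10, and in monocyte-derived macrophage-like dissociation -0.062 (from 0.19). In AT2-like it gave Gdf15 1.97 (from -3.11). Taking members with at least 100 UMIs gave, in fibroblast-like, interferon 0.76 over WT PBS and alveolar fibroblast -0.84 over WT bleomycin. Taking members with at least 1 UMI gave, over WT bleomycin, in AT2-like transitional 0.69. A second clustering at resolution 1.0 gave, of fibroblast-like cells, 56.8% alveolar, 6.72% adventitial and 6.29% inflammatory in WT PBS, and 12.01% adventitial and 1.77% peribronchial in WT BLM, and 1.35% peribronchial and 8.53% inflammatory in Het BLM. Of the 281 inflammatory fibroblast-like cells of WT PBS in that second clustering, 268 lay in a sub-cluster with the club cell genes Scgb3a2, Scgb3a1 and Scgb1a1 among its leading genes, so the name is poorly borne out there. The same sub-cluster held 205 of 484 in WT bleomycin and 228 of 498 in Het bleomycin.

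Chosen after seeing the data were the following. Leaving out the clusters led by Grem1 and by Hmga2 gave, over WT PBS, for shares fibroblast-like -1.71, and in fibroblast-like matrix 1.13, alveolar fibroblast -0.63, interferon 1.19 and cell division 1.77. This setting gave, over WT bleomycin, for shares fibroblast-like 0.37. Further values over WT bleomycin were, in fibroblast-like matrix 0.54, alveolar fibroblast -0.90, p53 0.062 (from -0.18), BCAA 0.10 (from -0.10), oxidative phosphorylation -0.14 (from 0.077), interferon -1.40 and cell division 0.29. Leaving out sub-clusters with Grem1 or Tnn among their leading genes gave, over WT PBS, in fibroblast-like matrix 1.247, alveolar fibroblast -0.83, interferon 1.08 and cell division 3.08. This setting gave, over WT bleomycin, in fibroblast-like matrix 0.51, alveolar fibroblast -1.27, p53 0.038 (from -0.18) and cell division 1.78. Naming rules 1 and 2 gave, over WT PBS, for shares fibroblast-like -1.70, and in fibroblast-like matrix 1.10. Over WT bleomycin they gave 0.14 and 0.47. Naming rules 3 and 4 gave, over WT bleomycin, for shares fibroblast-like 1.15, and in fibroblast-like matrix 0.35. A common doublet threshold gave, in fibroblast-like interferon, 0.70 over WT PBS and -1.79 over WT bleomycin. Naming rule 5 for sub-clusters gave, of fibroblast-like cells, 21.1% adventitial in WT PBS, and 17.1% adventitial in WT BLM, and 15.9% adventitial and 32.4% inflammatory in Het BLM.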

Other observations

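Lists of metabolism were read first over all cells. In WT bleomycin over WT PBS glycolysis had 6 higher and 1 lower of 18 (0.49 [0.46 to 0.54], percentile 99.8), with the enolase Eno1 3.01-fold higher (2.91 to 3.11), Pfkfb3, which drives the committed step, 1.71-fold lower (1.61 to 1.82) and Gapdh, the most expressed, 1.77-fold higher (1.75 to 1.80). Oxidative phosphorylation had 3 higher and 0 lower of 23 (0.35 [0.34 to 0.38], percentile 98.4), with the cytochrome oxidase subunits Cox5a 2.05-fold higher (2.02 to 2.09) and Cox4i1, the most expressed, 1.40-fold higher (1.39 to 1.42), and Ndufa4 1.11-fold lower (1.09 to 1.12). Amino acid transport and sensing had 6 higher and 1 lower of 20 (0.26 [0.18 to 0.31], percentile 97.1), with the transporters Slc7a8 2.66-fold higher (2.37 to 2.996), Slc43a1 2.23-fold lower (1.89 to 2.64) and Slc3a2, the most expressed, 1.27-fold higher (1.24 to 1.31). The ATF4 response to amino acid lack had 4 higher and 7 lower of 20 (-0.12 [-0.31 to 0.075], percentile 16.7), with the cystine carrier Slc7a11 2.45-fold higher (2.23 to 2.70), Atf5 5.17-fold lower (4.97 to 5.39) and Nupr1, the most expressed, 1.54-fold lower (1.52 to 1.57). In alveolar macrophage-like cells it had 1 higher and 8 lower of 18 (-0.57 [-0.64 to -0.48], percentile 0.290), with Slc7a11 2.54-fold higher (2.13 to 3.06), Atf5 6.09-fold lower (5.31 to 7.001) and Cebpb, the most expressed, 1.47-fold lower (1.44 to 1.51). In blood endothelial-like cells it had 2 higher and 6 lower of 18 (-0.47 [-0.60 to -0.23], percentile 0.510), with Slc7a11 3.41-fold higher (1.16 to 13.6), Chac1 2.94-fold lower (1.34 to 6.78) and Atf4, the most expressed, 1.49-fold lower (1.37 to 1.62). In fibroblast-like cells it had 6 higher and 7 lower of 19 (0.20 [-0.15 to 0.35], percentile 84.9), with Asns 5.37-fold higher (3.98 to 7.28), Atf5 2.61-fold lower (2.47 to 2.77) and Nupr1, the most expressed, 1.27-fold higher (1.24 to 1.30). In Het over WT bleomycin the ATF4 list had 7 higher and 0 lower of 20 (0.23 [0.15 to 0.27], percentile 97.45), with the proline enzyme Pycr1 2.64-fold higher (2.27 to 3.09), the serine enzyme Phgdh 1.23-fold lower (1.17 to 1.30) and Nupr1 2.02-fold higher (1.99 to 2.05). Amino acid transport had 2 higher and 1 lower of 20 (0.24 [0.20 to 0.29], percentile 96.2), with Slc43a1 2.12-fold higher (1.81 to 2.48), Slc7a7 1.71-fold lower (1.60 to 1.83) and Lamtor1, the most expressed, 1.11-fold higher (1.09 to 1.14). Glycolysis had 0 higher and 0 lower of 18 (-0.099 [-0.13 to -0.075], percentile 15.4), with Pgam1 1.13-fold higher (1.11 to 1.15), Pfkfb3 1.49-fold lower (1.40 to 1.60) and Gapdh 1.06-fold lower (1.05 to 1.07). Oxidative phosphorylation had 0 higher and 0 lower of 23 (-0.15 [-0.17 to -0.13], percentile 7.41), with Ndufa4 1.31-fold higher (1.29 to 1.33), the electron carrier Cycs 1.49-fold lower (1.45 to 1.54) and Cox4i1 1.28-fold lower (1.27 to 1.29). Values over all cells also carry the mix of classes. Within classes, over WT PBS, medians ran from 0.19 in fibroblast-like to 0.54 in blood endothelial-like cells for glycolysis, from 0.046 in blood endothelial-like to 0.40 in AT2-like cells for oxidative phosphorylation and from -0.028 in blood endothelial-like to 0.33 in AT2-like cells for amino acid transport. Over WT bleomycin they ran from -0.23 in AT2-like to 0.20 in monocyte-derived macrophage-like cells for glycolysis, from -0.18 in alveolar macrophage-like to 0.077 in fibroblast-like cells for oxidative phosphorylation, from 0.047 in blood endothelial-like to 0.35 in AT2-like cells for amino acid transport and from 0.076 in alveolar macrophage-like to 0.21 in blood endothelial-like cells for the ATF4 list. Some of these turned direction with another choice. Over WT PBS glycolysis of fibroblast-like cells came to -0.074 with each cell classed by its own marker score, and amino acid transport of AT2-like cells to -0.38 with cells thinned to 1000 UMIs. Over WT bleomycin amino acid transport of AT2-like cells came to -0.058 with the mean of each cell's CPM, and oxidative phosphorylation of fibroblast-like cells to -0.14 without the clusters led by Grem1 and by Hmga2. Glycolysis over all cells came to 0.042 with thinned cells.

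Some genes were chosen after their values were seen. Over all cells, in CPM, the olfactory receptor gene Or2n1c stood at 0, 0 and 24.3, with 0 UMIs in both wild-type libraries. In Het bleomycin it was 22.8 in fibroblast-like, 24.2 in AT2-like, 24.1 in alveolar macrophage-like and 28.0 in blood endothelial-like cells. The levels of H2-Q7 and H2-Q6 were given above. A variant of another strain near the H2 genes was not tested for. Some genes known from fat tissue were taken without a fixed list, with Fabp4 at 34.7, 86.1 and 97.6, Cfd at 0.945, 0.0134 and 41.1, Adipoq at 0.0746, 0.0134 and 0.631, Car3 at 0.186, 0.0806 and 1.56 and Retn at 0.286, 0.255 and 1.95. The heart muscle gene Actc1 was 29.0, 24.8 and 13.5. In fibroblast-like cells, of genes leading clusters, Spp1 was 8.5, 8776 and 24402 and Grem1 0.024, 110 and 241. Hmga2 was 0.071, 11.8 and 73.2 there and the activin gene Inhba 9.53, 167 and 164.

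Of the tests on Bcat2, the place among like genes was chosen before its result was seen, and the others after. Among the 500 genes nearest in expression, the Het over WT bleomycin ratio of Bcat2 lay at percentile 5.80, above the bound of 2.5, so by itself this did not exclude a difference in depth or scaling. The log2 ratio was -0.76 with TMM scaling and -0.55 with cells thinned to 1000 UMIs, and the upper bound nearer to 0 was -0.19. So neither of these corrections removed the whole difference, though the bound covers counting error only. A difference between the libraries that these settings do not correct is not excluded. The log2 ratio from the mix of classes alone was -0.010, which excludes a different mix of these classes as the cause. A different mix of clusters within a class was not tested. The median of all genes, -0.0074, decides nothing on a shift common to all genes, since CPM removes one. The ratio of 0.541 lay under the bound of 0.75 set for a heterozygous genotype. With 1 library per group, the genotype cannot be told apart from a difference between animals or libraries.

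For the lower interferon genes of Het bleomycin, free RNA and the mix of clusters were tests chosen before their results were seen, the mix as whole cause and the genotype after. Of 18 members, 14 were lower in fibroblast-like cells by more than their level in the class with the least of them, which excludes free RNA as the source of most. Within the 5 fibroblast-like clusters with at least 50 cells in both bleomycin libraries the medians were -1.73, -0.84, -1.60, -0.65 and -2.09, the nearest to 0, -0.65, above 0.5 times the class median, so a different mix could be part of the cause. The upper bound of that median was -0.40, so a different mix of these 5 clusters did not account for the whole difference. That bound covers counting error only, and a different mix of cells within a cluster was not tested. Over all cells the median was -1.37, and genotype, animal and library cannot be told apart with 1 library each.

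For the clusters led by Grem1 and by Hmga2, the doublet test was chosen before its result was seen and the others after. These cells were 0.0214%, 3.69% and 24.2% of the libraries. Their ratio to other fibroblast-like cells was 5.05-fold higher in Het than in WT bleomycin. Picked for this excess, they cannot exclude a lack of other types. Their median doublet score lay at percentile 57.9 of the kept Het bleomycin cells, which gave no sign of doublets. Called doublets had already been removed from those cells, so this cannot exclude doublets that were not called. Their median UMI number of 13628 was above the 6476 of other fibroblast-like cells. Of these cells 92.2% came from Het bleomycin. Genotype, animal and library each exist once and cannot be told apart.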
